A study of Mus musculus with 16 samples.

How the data were processed

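Gene expression was measured by RNA sequencing in spinal cord of adult female mice aged 12 weeks, of a strain that the labels spell C57BL7J. Per the series' design text, the lumbar cord was injured at L1/L3 by contusion and compression with an 8 g Fejota clip, and profiled on day 30. The uninjured libraries carry the time label of the injured ones, 30 days after injury, and were taken as uninjured from their group label. Per the labels' protocols, the 9 mm around the injury were divided into 3 pieces of 3 mm: the epicenter, the piece rostral to it (above) and the piece caudal to it (below). In uninjured animals the 9 mm of the same levels, T11 to S1, were processed as 1 piece, so this control pools the levels that the injured cord gives as 3 groups. Each of the 4 groups holds 4 libraries, numbered 1 to 4 in the labels. The labels do not say whether the libraries of a group come from separate animals or which segments come from the same cord, so the p-values measure only the spread between these samples, which may be technical, and the tests treat segments as independent.

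Total RNA was prepared with RNA Stat60 and libraries were made from 200 ng with the TruSeq RNA Sample Prep Kit v2, per the labels' protocols; this kit does not mark the strand. The authors deposited a table of raw read counts per gene, with 1 column per library and no normalization, per the file headers. The submitters' processing notes name TopHat2 2.0.12, Subread 1.4.4, edgeR and the genome build mm10, with no role or order. The annotation release, the treatment of reads that match several places and the strand setting are not given in the sources used here. Reads of near-identical genes (Lyz2 with its paralog, the globins, immunoglobulin segments such as Igkc, the S100a and Ly6c families) may therefore be split or lost between copies, and reads of overlapping genes on either strand cannot be told apart. Of the 85 genes of interest, 25 share exonic bases with another gene in the GENCODE M21 annotation of GRCm38, the assembly behind mm10: Pmp2 shares 86.9% of its exonic bases with a gene model on the same strand, and Hoxa11 35.0%, Gm29629 22.3%, Nefm 19.2%, Hmgcs1 12.1% and Idi1 9.22% with genes on the opposite strand, while Hoxc10 shares 8.70% on the same strand.

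The table holds 43346 gene rows; 80 rows whose name repeats were given their identifier as a name. Rows were kept with edgeR's filterByExpr by group, which left 23769 rows with at least 99.97% of the counts of every library. The 37 rows of the mitochondrial chromosome hold 0 counts in all 16 libraries, so mitochondrially encoded genes are not measured. The share of 3 rows known to take reads of ribosomal RNA type, Lars2 among them, is given as a sign of how much ribosomal RNA remained. Library totals ran from 65.6 to 90.0 M (mega) counts; a count of 3, the most that a count of 0 allows at 95% confidence, corresponds to 0.0316 to 0.0485 CPM in a single library. Such floors and the counting intervals cover counting error only, since reads are not independent molecules.

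Counts were scaled with trimmed mean of M-values (TMM) factors and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test (glmQLFit and glmQLFTest), in 1 fit of all 16 libraries with a term per group and no covariate, for all 6 pairs of groups. P-values were adjusted by the Benjamini-Hochberg method over the tested rows of each comparison, and a gene is called, and said to rise, fall or change, at an adjusted p under 0.05. CPM values are scaled with the same factors and are given as mean ± SD (n = 4 per group); a log2 fold change is given ± SE, the SE being its size over the square root of F. The step was tested on simulated counts for the comparison of epicenter with uninjured cord: of 23769 genes, 200 were changed, and it recovered 40% of the 100 changed 1.5-fold and 78% of the 100 changed 2-fold, with 7.09% of its calls false. A gene is called specific to a segment when it differs in the same direction from uninjured cord and from both other segments. Genes called in the same direction in a pair of segments against the same uninjured libraries were counted, beside the count for independent lists, the count in 20 simulations of unchanged groups and the counts with the uninjured libraries split 2 and 2.

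Before the data were examined, 42 gene lists with 576 members were fixed, of cell types, pathways, Hox genes by spinal level and other tissues (red blood cells, skeletal muscle, dorsal root ganglion, meninges and fat); 6 members were not found under their name. Each list was tested in each comparison with camera on limma-voom values (limma 3.58.1, preset correlation 0.01), adjusted over all 252 list tests; this test compares the list with the other genes. Camera with the correlation estimated from each list and fry, which tests whether a list's genes move one way on balance, were run beside it. With an estimated correlation 0 of the 252 tests passed, at 40 tests with an unadjusted p under 0.05 (lowest 0.00242), so each list call rests on the preset correlation; fry called 159, of which 145 were also called by camera. Counts of members "adjusted over the list alone" use the same edgeR p-values adjusted within the list.

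The genes named follow a rule fixed at the same time: per comparison, the 6 largest increases and 6 largest decreases among genes with an adjusted p under 0.05, a mean of at least 1 log2 CPM and non-overlapping groups, passing over models without a symbol, with predicted names or ending in Rik; up to 4 members with the smallest adjusted p of each list called by camera; and 25 fixed genes. The text prints part of these genes, chosen with their values known, mostly among those whose call no single left-out library ended, so the examples are steadier than the lists they come from, whose counts cover all members. Other members of the lists may be named as examples, and the results of some single genes are not reported here.

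Alternatives fixed before the data were examined were size factors of the DESeq2 type (RLE), upper-quartile factors, library totals alone, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom, glmTreat against a 1.5-fold change, only the libraries compared, the replicate number as a block, duplicateCorrelation and leaving out each library in turn.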

Results

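RNA of 16 spinal cord libraries was sequenced, 4 from uninjured cord and 4 each from the segments above, at (epicenter) and below a clip injury, 30 days after it. The series asks how gene expression in chronic spinal cord injury differs by region. Total counts averaged 73.5 ± 6.21 M (mega) in uninjured cord, 83.1 ± 8.11 M above, 75.6 ± 6.83 M at the epicenter and 79.7 ± 7.25 M below (SD, n = 4 each). Rows of ribosomal RNA type held 8.52 ± 0.604% of the counts in uninjured cord, 5.83 ± 0.878% above, 10.1 ± 2.28% at the epicenter and 5.23 ± 0.849% below.

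Replicates were closest in uninjured cord, where Spearman's rho between libraries across genes, which are not independent replicates, was at least 0.995, and least close below the injury, where it fell as low as 0.95. Uninjured libraries lay between -99.5 and -89.9 on the first principal component (66.4% of the variance) and epicenter libraries between 87.9 and 105.2. Of the segments above, replicate 1 lay at -18.1 and the others between -54.9 and -53.3. Of those below, replicate 3 lay at 112, and the others at -9.98, 34.2 and 42.1. Counts differed between every pair of replicates by more than sampling noise (chi-square per degree of freedom 6.83 to 717), so none was taken as 1 library deposited again.

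**Figure D1:**
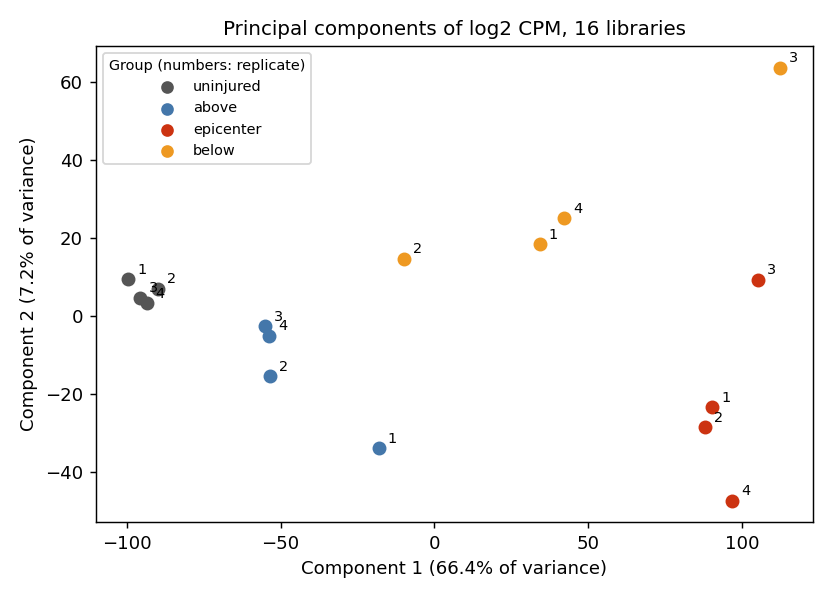
Principal components 1 and 2 of log2 CPM, with 1 point per library, colored by group and numbered by replicate. Uninjured libraries lie at the left, epicenter libraries at the right and below 3 apart from its group at 112.

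Of 23769 genes tested, 14565 differed between epicenter and uninjured cord (7593 higher, 6972 lower), 841 between the segment above and uninjured cord (735 higher, 106 lower) and 9346 between the segment below and uninjured cord (5603 higher, 3743 lower). Between segments, 12517 differed between epicenter and above (6725 higher at the epicenter, 5792 lower), 5062 between epicenter and below (2626 higher, 2436 lower) and 5788 between above and below (2165 higher above, 3623 lower). Scaling by library totals alone shifted the median of all genes below against uninjured cord by 0.141 on the log2 scale, and it raised the share of higher genes there from 60% to 84.3% (7615 higher, 1421 lower). The same scaling lowered that share from 51.9% to 30.7% for epicenter against below (1652 higher, 3729 lower) and from 37.4% to 15.3% for above against below (953 higher, 5294 lower). Upper-quartile factors gave 41.1% for epicenter against below (2038 higher, 2925 lower).

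**Figure D2:**
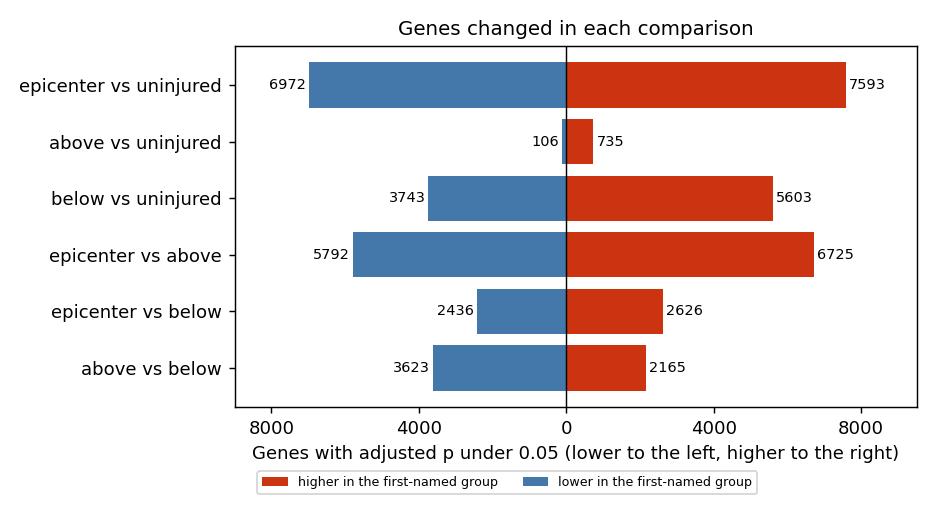
Number of genes with an edgeR adjusted p under 0.05 in each of the 6 comparisons, higher in the first-named group to the right and lower to the left. Against uninjured cord, bars show 735 higher and 106 lower genes above and 7593 and 6972 at the epicenter.

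At the epicenter, genes of phagocytes, reactive astrocytes and immune signaling were higher than in uninjured cord. Gpnmb, a glycoprotein of lipid-laden phagocytes (mm10 chromosome 6, 49036518 to 49058182), rose from 2.71 ± 1.07 to 974 ± 331 CPM (SD, n = 4 each). Its log2 fold change was 8.49 ± 0.78 (SE), with edgeR adjusted p = 8.11e-07. Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, and Mmp12, macrophage elastase, were among the 6 largest increases, at 10.93 ± 0.97 and 8.56 ± 0.67. All 16 measured genes of phagocytic microglia and macrophages rose, 16 of them adjusted over the list alone. Camera gave this list adjusted p = 9.50e-09 (adjusted p = 0.395 with an estimated correlation). Among its members, Lyz2, lysozyme, rose by 7.88 ± 0.70, Itgax by 7.34 ± 0.59, Cst7 by 7.17 ± 0.53, Trem2 by 4.47 ± 0.41 and Cd68 by 5.55 ± 0.52. Of 12 genes of homeostatic microglia 9 rose and 3 did not pass, with 9 higher adjusted over the list alone. The microglia list had camera adjusted p = 4.08e-05 (adjusted p = 0.344 with an estimated correlation). Tmem119 rose by 1.71 ± 0.16 and Aif1, a pan-myeloid marker outside the list, by 3.3 ± 0.28. P2ry12, a receptor of resting microglia, did not pass (0.22 ± 0.10), although it did without below 3 (0.21). Reactive astrocyte genes rose in 17 of 17 cases (17 adjusted over the list alone). For this list camera gave adjusted p = 1.04e-09 (adjusted p = 0.371 with an estimated correlation). The intermediate filaments Gfap and Vim rose by 1.98 ± 0.28 and 4.28 ± 0.37, the protease inhibitor Serpina3n by 4.03 ± 0.37 and Lcn2, lipocalin 2, by 6.60 ± 0.47. Members of the lysosome and lipid lists rose in 15 and 13 of 16 and 14 cases and fell in 0 and 1, with 15 and 13 higher adjusted over the list alone. Tested with camera, they had adjusted p = 2.75e-06 and 8.00e-05 (adjusted p = 0.436 and 0.440 with an estimated correlation).

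Immune genes rose with them at the epicenter. All measured members rose in the lists of antigen presentation (15), complement (14), interferon response (17) and cytokines and chemokines (18). As many passed adjusted over the list alone (15, 14, 17 and 18). In this order camera gave adjusted p = 8.58e-10, 9.50e-09, 3.37e-06 and 3.43e-08 (adjusted p = 0.300, 0.300, 0.413 and 0.290 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, went from 2.59 ± 0.867 to 124 ± 5.21 CPM (5.57 ± 0.39, edgeR adjusted p = 2.25e-07). C3 rose by 3.13 ± 0.34, C4b by 2.48 ± 0.16, Gbp2 by 3.28 ± 0.22 and the chemokine Ccl4 by 5.57 ± 0.36. The cytokine list had a median of 4.98, or 4.79 with members that had no counts in a group set to their bound. Genes of monocytes and border macrophages, T and NK cells, B and plasma cells and neutrophils rose in 14, 14, 8 and 11 of 14, 16, 11 and 11 cases. Higher adjusted over the list alone were 14, 15, 8 and 11, and 1 T and NK cell gene fell. For these lists camera gave adjusted p = 7.13e-06, 2.62e-05, 0.0116 and 1.82e-04 (adjusted p = 0.300, 0.278, 0.371 and 0.438 with an estimated correlation). Igkc, the kappa light chain constant region, rose by 5.06 ± 0.49. Red blood cell and proliferation genes rose in 7 and 12 of 7 and 12 cases (7 and 12 adjusted over the list alone). Their camera tests gave adjusted p = 1.09e-05 and 4.10e-06 (adjusted p = 0.300 and 0.371 with an estimated correlation). Top2a and Mki67, of dividing cells, rose by 4.09 ± 0.35 and 3.79 ± 0.37.

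Genes of fibrous matrix, vessels and peripheral myelin were also higher at the epicenter. Fibroblast and matrix genes rose in 18 of 18 cases (18 adjusted over the list alone). The fibroblast list had camera adjusted p = 1.24e-10 (adjusted p = 0.330 with an estimated correlation). Col1a1 and Col3a1, chains of fibrillar collagen, rose by 6.39 ± 0.73 and 7.17 ± 0.89, and Postn, periostin, went from 1.33 ± 0.283 to 161 ± 70.0 CPM. Schwann cell genes rose in 14 of 14 cases (14 adjusted over the list alone). The Schwann list had camera adjusted p = 7.36e-08 (adjusted p = 0.300 with an estimated correlation). Pmp22, a peripheral myelin protein, rose by 3.04 ± 0.24 and Drp2 by 1.41 ± 0.13. Meningeal genes, of another tissue, rose in 10 of 11 cases (10 adjusted over the list alone), with camera adjusted p = 4.29e-04 (adjusted p = 0.436 with an estimated correlation). Dorsal root ganglion genes, also of another tissue, rose in 7 of 8 cases and 7 adjusted over the list alone (camera adjusted p = 0.188). Without epicenter 4, 4 of them rose and 1 fell. For endothelium and for pericytes and smooth muscle, 9 and 8 of 14 and 10 members rose and 0 and 1 fell, with 9 and 8 higher adjusted over the list alone. The vessel lists had camera adjusted p = 0.0122 and 0.0159 (adjusted p = 0.549 and 0.510 with an estimated correlation), and without uninjured 3 the pericyte count was 5.

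Genes of myelin, cholesterol synthesis, neurons and respiration fell at the epicenter. All 19 measured genes of cholesterol synthesis fell (19 adjusted over the list alone). The cholesterol list had camera adjusted p = 1.13e-11 (adjusted p = 0.290 with an estimated correlation). Hmgcs1, which makes HMG-CoA, went from 401 ± 14.5 to 134 ± 7.64 CPM (-1.59 ± 0.12), and Sqle, squalene epoxidase, and Idi1 stood at -1.45 ± 0.09 and -1.62 ± 0.13. Genes of myelinating oligodendrocytes fell in 10 of 16 cases and rose in 1 (10 lower adjusted over the list alone). The myelin list had camera adjusted p = 0.00246 (adjusted p = 0.451 with an estimated correlation). Ermn fell by 0.98 on the log2 scale, and Mbp did not pass (0.05 ± 0.13). General neuronal genes fell in 12 of 14 cases, glutamatergic genes in 11 of 13, GABA and glycine genes in 13 of 13 and voltage-gated channels in 15 of 15. Adjusted over the list alone, 13, 12, 13 and 15 were lower. Camera gave these lists adjusted p = 8.19e-04, 4.72e-04, 1.82e-04 and 6.88e-05 (adjusted p = 0.502, 0.438, 0.451 and 0.451 with an estimated correlation). Gabrb2, a GABA receptor subunit, went from 39.7 ± 4.58 to 6.61 ± 2.44 CPM (-2.58 ± 0.48, edgeR adjusted p = 2.87e-04). Glra3, a glycine receptor subunit, stood at -2.52 ± 0.46, Kcna2, a potassium channel, at -1.88 ± 0.32 and Oprm1, the mu opioid receptor, at -2.60 ± 0.57. Motor and other cholinergic neuron genes fell in 6 of 12 cases and rose in 2 (6 lower adjusted over the list alone). This list had camera adjusted p = 0.0464 (adjusted p = 0.517 with an estimated correlation). Oxidative phosphorylation genes fell in 11 of 15 cases (11 adjusted over the list alone), with camera adjusted p = 0.00158 (adjusted p = 0.512 with an estimated correlation). The motor neuron call ended without below 2 or 3, epicenter 1, 2 or 3 or uninjured 4 (camera adjusted p = 0.0593, 0.0623, 0.0529, 0.0559, 0.108 and 0.0534) and with upper-quartile factors (0.0612).

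Genes of the dorsal horn fell in 6 of 14 cases and rose in 1 (8 lower adjusted over the list alone, camera adjusted p = 0.0941). The count of lower genes was 3 without uninjured 2, 3 or 4 or epicenter 1, 3 or 4, and 10 without below 3. Hox genes mark the level of the cord along its axis. Those of lumbar and sacral level were lower at the epicenter in 8 of 11 cases (8 adjusted over the list alone). This Hox list had camera adjusted p = 0.00176 (adjusted p = 0.432 with an estimated correlation). Hoxc12 was at 3.47 ± 0.897 CPM in uninjured cord and 0.0125 ± 0.0145 CPM at the epicenter. Of 15 thoracic-level Hox genes 3 rose and 4 fell, as did 3 and 4 adjusted over the list alone (camera adjusted p = 0.252). Hoxc8, of that level, fell from 48.5 ± 2.45 to 31.6 ± 4.64 CPM. These thoracic counts became 2 and 2 without uninjured 3 or 4, 1 and 3 without epicenter 4 and 3 and 8 without below 3.

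Above the injury, fewer genes differed from uninjured cord, and those of interferon response, cytokines, antigen presentation and reactive glia were among them. Itgax, an integrin of activated microglia, rose from 0.40 ± 0.153 to 16.2 ± 1.05 CPM (SD, n = 4 each), a log2 fold change of 5.33 ± 0.56 (SE) with edgeR adjusted p = 9.03e-05. Cst7 rose by 4.70 ± 0.50, and Mmp12 by 6.06 ± 0.66, a call that limma-voom did not make. Interferon response genes rose in 17 of 17 cases, cytokines and chemokines in 14 of 18, antigen presentation in 12 of 15 and complement in 10 of 14. Passing adjusted over the list alone were 17, 17, 14 and 11. In this order camera gave adjusted p = 1.86e-18, 1.35e-19, 2.98e-14 and 3.36e-13 (adjusted p = 0.278, 0.221, 0.278 and 0.278 with an estimated correlation). Oasl2, Bst2 and Cxcl10, induced by interferon, rose by 2.11 ± 0.32, 2.28 ± 0.31 and 3.79 ± 0.42. Ccl4 rose by 4.36 ± 0.36, C4b by 1.85 ± 0.16 and Cd74 by 2.41 ± 0.35. Reactive astrocyte genes rose in 14 of 17 cases, phagocytic genes in 11 of 16 and homeostatic microglia genes in 10 of 12, with 17, 15 and 10 adjusted over the list alone. For these lists camera gave adjusted p = 1.12e-21, 1.86e-18 and 4.37e-14 (adjusted p = 0.278, 0.278 and 0.221 with an estimated correlation). Gfap rose by 1.37 ± 0.28, Vim by 2.62 ± 0.35, Serpina3n by 2.38 ± 0.35 and Gpnmb by 3.69 ± 0.64. The cytokine median was 3.40, or 2.93 with members that had no counts in a group set to their bound.

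Some blood cell and proliferation genes also rose above the injury. Counts of risen genes were 7, 6, 6, 3 and 2 of 12, 7, 11, 14 and 16 for proliferation, red blood cells, neutrophils, monocytes, and T and NK cells, and 10, 7, 9, 9 and 6 adjusted over the list alone. Camera gave these lists adjusted p = 5.77e-10, 7.22e-13, 9.97e-04, 1.31e-04 and 0.00264 (adjusted p = 0.278, 0.221, 0.455, 0.371 and 0.388 with an estimated correlation). The neutrophil count was at most 1 without any 1 uninjured library or above 4, whose list mean stood apart (0.23 log2 CPM against -1.40 to -1.25), and 4 without above 1. Fibroblast, pericyte, lipid and lysosome genes rose in 3, 2, 3 and 3 of 18, 10, 14 and 16 cases (9, 4, 10 and 6 adjusted over the list alone). Tested with camera, they had adjusted p = 3.38e-05, 0.00423, 1.17e-05 and 1.14e-07 (adjusted p = 0.449, 0.451, 0.412 and 0.412 with an estimated correlation). Above 1 stood apart in the list of fibroblasts and fibrous matrix (4.87 against 3.44 to 3.51), whose median was 0.29 without it in place of 0.99 (camera adjusted p = 0.00462). Genes of cholesterol synthesis fell in 4 of 19 cases (11 adjusted over the list alone), with camera adjusted p = 5.61e-13 (adjusted p = 0.278 with an estimated correlation). In 15 lists, neurons, myelin and Schwann cells among them, edgeR called 0 of 199 members, where 25 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 6 and 1. Meningeal genes, of which edgeR called 0 and 8 adjusted over the list alone, had camera adjusted p = 0.00903 (adjusted p = 0.510 with an estimated correlation). That p was 0.361 without above 1. In the endothelium and thoracic-level Hox lists 1 and 1 of 14 and 15 members rose, 1 and 2 adjusted over the list alone (camera adjusted p = 0.202 and 0.188).

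Lumbar and sacral Hox genes were lower above the injury than in uninjured cord, which was processed as 1 piece over all levels. Of 11 such genes 9 were lower (9 adjusted over the list alone), with camera adjusted p = 3.61e-18 (adjusted p = 0.221 with an estimated correlation). Their median was -7.85, or -5.33 with members that had no counts in a group set to their bound. Hoxd10 (mm10 chromosome 2, 74691924 to 74695105) was at 18.2 ± 2.01 CPM in uninjured cord and 1.01 ± 0.487 CPM above (-4.19 ± 0.38, edgeR adjusted p = 2.39e-05). Hoxa11 held 1201 counts over the uninjured libraries and 1 above, a ratio of 1400 (95% counting interval 251 to 55343). Hoxc12 held 989 and 1, a ratio of 1153 (206 to 45582). Without uninjured 1 to 4, above 1 and below 3, the number of genes that differed was 408, 470, 416, 479, 476 and 2298, in place of 841. A fit of only the libraries compared gave 3684, limma-voom with library weights 3552, leaving out above 1 and below 3 together 1661, DESeq2 1464, duplicateCorrelation 278, limma-voom 269 and glmTreat 252. Leaving out a library moved the count of called genes over 1.5 times in 18, 15, 16 and 13 of the 27 lists with calls for uninjured 1 to 4 and in 14, 7, 8 and 8 for the replicates above. For the epicenter and below replicates it did so in 5, 6, 5 and 5 and in 6, 6, 12 and 1 lists, upward for below 2 and 3 and downward for the rest.

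Below the injury, phagocyte, matrix and Schwann cell genes were higher than in uninjured cord, and cholesterol synthesis and myelin genes lower. Mmp12 rose from 0.0739 ± 0.0627 to 32.1 ± 21.6 CPM (SD, n = 4 each), a log2 fold change of 8.72 ± 0.67 (SE) with edgeR adjusted p = 1.05e-06, and Atp6v0d2 by 11.31 ± 0.97. All measured genes rose for phagocytic microglia and macrophages (16), reactive astrocytes (17), antigen presentation (15), complement (14), interferon response (17) and cytokines (18). Adjusted over the list alone, 16, 17, 15, 14, 17 and 18 were higher. In this order camera gave adjusted p = 2.36e-11, 3.17e-12, 3.17e-12, 3.00e-11, 2.08e-07 and 3.70e-10 (adjusted p = 0.344, 0.300, 0.278, 0.278, 0.409 and 0.278 with an estimated correlation). Cd74 rose by 4.92 ± 0.38, C4b by 2.27 ± 0.16 and Gfap by 1.58 ± 0.28. Homeostatic microglia, monocyte, T and NK cell, neutrophil, red blood cell and proliferation genes rose in 9, 14, 13, 9, 7 and 11 of 12, 14, 16, 11, 7 and 12 cases (9, 14, 13, 10, 7 and 11 adjusted over the list alone). Camera gave these lists adjusted p = 1.03e-05, 7.86e-08, 4.74e-06, 8.72e-04, 4.10e-06 and 5.79e-06 (adjusted p = 0.300, 0.278, 0.278, 0.451, 0.290 and 0.371 with an estimated correlation). B and plasma cell genes rose in 7 of 11 cases (7 adjusted over the list alone, camera adjusted p = 0.0861). Lysosome, lipid, fibroblast, endothelial, pericyte and meningeal genes rose in 15, 13, 18, 11, 7 and 9 of 16, 14, 18, 14, 10 and 11 cases (15, 13, 18, 11, 9 and 9 adjusted over the list alone). For these lists camera gave adjusted p = 7.87e-08, 8.14e-07, 2.36e-11, 1.72e-04, 6.35e-04 and 7.14e-05 (adjusted p = 0.412, 0.395, 0.300, 0.438, 0.415 and 0.412 with an estimated correlation). Below 3 stood apart in the lists of endothelium (5.84 log2 CPM against 4.94 to 5.03) and of pericytes and smooth muscle (4.88 against 3.81 to 3.91), whose medians were 0.41 and 0.57 without it in place of 0.71 and 0.97. Schwann cell genes rose in 13 of 14 cases (13 adjusted over the list alone), with camera adjusted p = 1.65e-11 (adjusted p = 0.278 with an estimated correlation). Pmp22 rose by 2.92 ± 0.24 and Drp2 from 63.0 ± 4.77 to 283 ± 35.6 CPM. edgeR called 0 of 8 dorsal root ganglion genes, 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

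Genes of cholesterol synthesis fell below the injury in 19 of 19 cases (19 adjusted over the list alone), with camera adjusted p = 1.96e-18 (adjusted p = 0.278 with an estimated correlation). Hmgcs1 was at 146 ± 29.6 CPM (-1.46 ± 0.12), and Sqle stood at -1.32 ± 0.09. Myelin genes fell in 11 of 16 cases and oxidative phosphorylation genes in 14 of 15 (11 and 14 adjusted over the list alone). Tested with camera, they had adjusted p = 6.23e-06 and 5.14e-06 (adjusted p = 0.371 and 0.413 with an estimated correlation). General neuronal, motor neuron, glutamatergic, GABA and glycine and voltage-gated channel genes fell in 9, 6, 4, 4 and 5 of 14, 12, 13, 13 and 15 cases, and 1 motor neuron gene rose (11, 7, 2, 3 and 5 lower adjusted over the list alone). Their camera tests gave adjusted p = 1.04e-04, 0.00129, 0.00176, 7.29e-04 and 1.75e-04 (adjusted p = 0.451, 0.412, 0.451, 0.488 and 0.458 with an estimated correlation). Chat, which makes acetylcholine, stood at -1.03 ± 0.20, Chodl at -2.05 ± 0.31 and Nefm, a neurofilament, at -1.24 ± 0.29. Dorsal horn genes rose in 3 and fell in 1 of 14 cases (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.637). Thoracic-level Hox genes fell in 7 of 15 cases (7 adjusted over the list alone), with camera adjusted p = 9.00e-05 (adjusted p = 0.371 with an estimated correlation). Hoxc8 went from 48.5 ± 2.45 to 13.4 ± 0.886 CPM. Lumbar and sacral ones rose in 2 of 11 cases (1 adjusted over the list alone, camera adjusted p = 0.367), Hoxa11 by 1.15 ± 0.26. Leaving out a library moved the count of called genes over 1.5 times in 9, 7, 6 and 7 of the 41 lists with calls for uninjured 1 to 4, in 3, 4, 5 and 6 for those below, 1, 2, 3 and 1 for those above and 2, 2, 0 and 1 for the epicenter. GABA and glycine genes went from 4 lower to 2 without any uninjured library or below 4, and to 10 and 9 without below 2 and 3. Below 3 stood apart in the lists of excitatory glutamatergic transmission (3.74 log2 CPM against 5.35 to 5.54), inhibitory GABA and glycine transmission (4.56 against 6.58 to 6.95), the dorsal horn and thoracic-level Hox genes. Without it the medians of the first pair were -0.31 and -0.48 in place of -0.64 and -0.80.

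**Figure D3:**
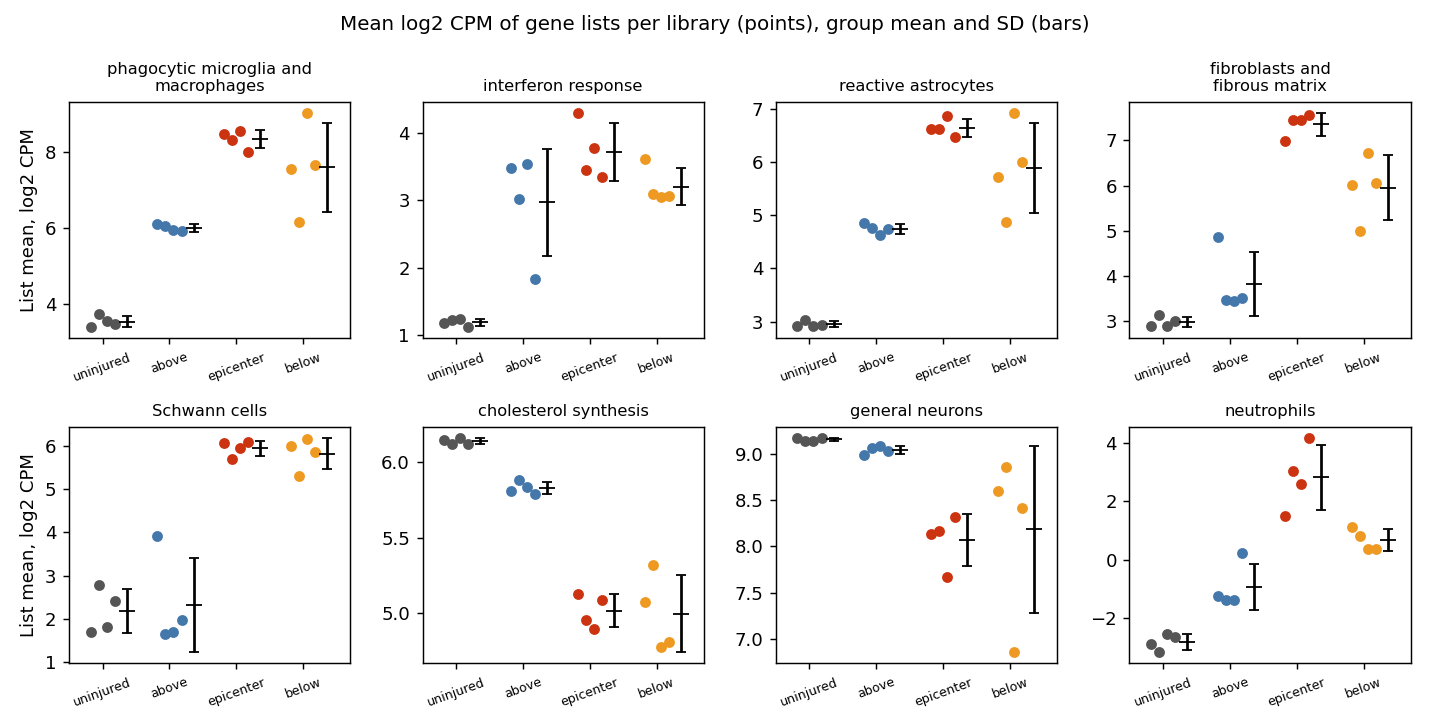
Mean log2 CPM of 8 gene lists in each library (points), with the mean and SD of each group of 4 beside them. Phagocyte, astrocyte and interferon genes are higher in each injured segment than in uninjured cord, cholesterol synthesis genes are lower in each, and Schwann cell genes are higher at the epicenter and below.

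Between the injured segments, the epicenter held higher levels of matrix, Schwann cell and immune genes than the segment above. Sfrp4, a secreted Wnt-binding protein, was at 201 ± 48.9 CPM at the epicenter and 1.74 ± 0.555 CPM above (SD, n = 4 each), a log2 fold change of 6.86 ± 0.57 (SE) with edgeR adjusted p = 2.69e-06. Fibroblast and Schwann cell genes were higher in 18 and 14 of 18 and 14 cases (18 and 14 adjusted over the list alone). Tested with camera, they had adjusted p = 5.32e-12 and 3.15e-09 (adjusted p = 0.300 and 0.290 with an estimated correlation). Postn stood at 4.51 ± 0.45 and Col6a3 at 3.14 ± 0.24. For phagocytic genes, monocytes, T and NK cells, B and plasma cells, neutrophils and red blood cells, 16, 14, 15, 7, 11 and 7 of 16, 14, 16, 11, 11 and 7 were higher (16, 14, 15, 7, 11 and 7 adjusted over the list alone). Camera gave these lists adjusted p = 3.46e-07, 1.19e-06, 1.09e-05, 0.00145, 2.01e-05 and 1.18e-04 (adjusted p = 0.412, 0.290, 0.278, 0.298, 0.412 and 0.359 with an estimated correlation). Lcn2 was higher by 4.14 ± 0.41 and Cd79a, part of the B cell receptor, by 3.07 ± 0.35. Reactive astrocyte, antigen presentation, complement, cytokine, homeostatic microglia and proliferation genes were higher in 16, 15, 14, 17, 9 and 12 of 17, 15, 14, 18, 12 and 12 cases (17, 15, 14, 18, 9 and 12 adjusted over the list alone). For these lists camera gave adjusted p = 4.14e-07, 1.93e-09, 9.09e-08, 3.33e-06, 0.0122 and 5.80e-05 (adjusted p = 0.412, 0.300, 0.300, 0.329, 0.455 and 0.412 with an estimated correlation). Lysosome, lipid, endothelial and meningeal genes were higher in 15, 12, 7 and 6 of 16, 14, 14 and 11 cases and 1 endothelial gene was lower (15, 12, 7 and 7 higher adjusted over the list alone). In this order camera gave adjusted p = 3.35e-05, 1.43e-04, 0.0196 and 2.34e-04 (adjusted p = 0.451, 0.449, 0.576 and 0.416 with an estimated correlation). Pericyte and dorsal root ganglion genes were higher in 4 and 5 of 10 and 8 cases (4 and 5 adjusted over the list alone, camera adjusted p = 0.0653 and 0.252). The meningeal and pericyte counts were 10 and 6 without above 1, with pericytes at 5 and 7 without epicenter 3 and below 3.

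Cholesterol synthesis, myelin, respiration and neuronal genes were lower at the epicenter than above. They were lower in 19, 10 and 11 of 19, 16 and 15 cases for cholesterol synthesis, myelin and oxidative phosphorylation (19, 10 and 11 adjusted over the list alone). Their camera tests gave adjusted p = 3.70e-11, 1.70e-05 and 3.60e-04 (adjusted p = 0.290, 0.393 and 0.470 with an estimated correlation). General neuronal, glutamatergic, GABA and glycine and voltage-gated channel genes were lower in 14, 11, 13 and 13 of 14, 13, 13 and 15 cases (14, 11, 13 and 15 adjusted over the list alone). Tested with camera, they had adjusted p = 3.58e-04, 2.99e-04, 9.72e-05 and 4.90e-05 (adjusted p = 0.477, 0.432, 0.451 and 0.449 with an estimated correlation). Gabrb2 stood at -2.25 ± 0.47 and Glra3 at -1.96 ± 0.45, and the general neuronal count was 9 without above 2 and 7 without epicenter 3. Motor neuron genes were lower in 6 and higher in 2 of 12 cases (7 lower adjusted over the list alone, camera adjusted p = 0.0653). Lumbar and sacral Hox genes were higher at the epicenter in 4 of 11 cases (4 adjusted over the list alone, camera adjusted p = 0.194), Hoxd10 by 3.38 ± 0.37. The interferon, dorsal horn and thoracic-level Hox lists had camera adjusted p = 0.0190, 0.0421 and 0.0314 (adjusted p = 0.613, 0.630 and 0.517 with an estimated correlation). Their higher members were 5, 1 and 2 and their lower ones 0, 2 and 5 of 17, 14 and 15 (4, 1 and 2 and 0, 1 and 5 adjusted over the list alone). The interferon call ended without above 4 (camera adjusted p = 0.158) or epicenter 1 (0.0932), and the thoracic-level Hox call without epicenter 3 (0.0555). The dorsal horn call ended without above 1, epicenter 3 or epicenter 4 (0.0688, 0.135 and 0.0583) or with upper-quartile factors (0.0515). Interferon genes numbered 3 higher without epicenter 1, and thoracic-level Hox genes 0 and 2 higher and 4 and 9 lower without epicenter 4 and below 3. Dorsal horn genes numbered 5 and 11 lower without epicenter 2 and below 3, and 1 lower without above 1, 2 or 4 or epicenter 3 or 4.

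Against the segment below, the epicenter held higher levels of matrix, neutrophil, B cell and red blood cell genes. Aspn, a matrix proteoglycan, was at 23.4 ± 13.4 CPM at the epicenter and 2.10 ± 1.13 CPM below, a log2 fold change of 3.48 ± 0.49 (SE) with edgeR adjusted p = 0.00161. Fibroblast, neutrophil, B and plasma cell and red blood cell genes were higher in 11, 11, 7 and 7 of 18, 11, 11 and 7 cases (14, 11, 7 and 7 adjusted over the list alone). In this order camera gave adjusted p = 1.91e-08, 2.75e-06, 6.25e-04 and 1.41e-05 (adjusted p = 0.388, 0.395, 0.278 and 0.300 with an estimated correlation). Postn stood at 2.03 ± 0.40, Sfrp4 at 2.36 ± 0.46 and Cd79a at 1.47 ± 0.32. Antigen presentation, complement, cytokine, reactive astrocyte and proliferation genes were higher in 3, 1, 2, 5 and 4 of 15, 14, 18, 17 and 12 cases (8, 1, 2, 5 and 6 adjusted over the list alone). For these lists camera gave adjusted p = 3.19e-05, 9.17e-04, 1.17e-04, 1.82e-04 and 1.46e-04 (adjusted p = 0.412, 0.449, 0.409, 0.488 and 0.412 with an estimated correlation). Lumbar and sacral Hox genes were lower at the epicenter in 8 of 11 cases (9 adjusted over the list alone), with camera adjusted p = 2.13e-08 (adjusted p = 0.278 with an estimated correlation). Hoxa11 stood at -1.63 ± 0.26, and Hoxc8 was higher by 1.24 ± 0.09. Calca, the precursor of calcitonin gene-related peptide, was at 119 ± 83.1 CPM at the epicenter, where replicate 4 held 243 CPM and the others 64.6 to 90.9 CPM, and at 12.8 ± 6.13 CPM below. The lists of Schwann cells, cholesterol synthesis, myelin, general neurons, motor neurons, lipid, pericytes and meninges had 1, 3, 1, 0, 2, 1, 0 and 1 higher and 1, 2, 2, 2, 0, 1, 1 and 0 lower members. Adjusted over the list alone these were 1, 3, 0, 0, 2, 1, 0 and 0 and 1, 2, 1, 2, 0, 0, 1 and 0 (camera adjusted p = 0.83, 0.844, 0.744, 0.443, 0.650, 0.268, 0.966 and 0.0861). For cholesterol synthesis the median, mean and test differed in sign. edgeR called 0 of 16, 14, 16 and 15 phagocytic, endothelial, lysosomal and oxidative phosphorylation genes, where 0, 1, 2 and 5 had an unadjusted p under 0.05, DESeq2 called 0, 0, 0 and 3 and limma-voom 1, 0, 1 and 0. These lists had camera adjusted p = 0.00540, 0.453, 0.0791 and 0.807. For phagocytic genes camera gave adjusted p = 0.583 with an estimated correlation, and 0.137 without below 2 at the preset one.

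Genes of inhibitory and excitatory transmission, voltage-gated channels and the dorsal horn were lower at the epicenter than below in 3, 3, 5 and 4 of 13, 13, 15 and 14 cases, and 1 excitatory gene was higher (3, 5, 6 and 4 lower adjusted over the list alone). Camera gave these lists adjusted p = 0.00903, 0.0310, 0.0118 and 0.0359 (adjusted p = 0.576, 0.576, 0.585 and 0.616 with an estimated correlation). Glra3 stood at -2.0 ± 0.45 and Scn2a1, a sodium channel, at -1.27 ± 0.30. Homeostatic microglia, monocyte, T and NK cell, interferon, thoracic-level Hox and dorsal root ganglion genes were higher in 2, 2, 4, 1, 4 and 6 of 12, 14, 16, 17, 15 and 8 cases, and 1 T and NK cell gene was lower (2, 2, 4, 0, 4 and 7 higher adjusted over the list alone). Their camera tests gave adjusted p = 0.0107, 0.0464, 0.00649, 0.0197, 0.00354 and 0.0257 (adjusted p = 0.451, 0.528, 0.412, 0.613, 0.440 and 0.528 with an estimated correlation). The inhibitory call ended without below 2 (camera adjusted p = 0.0869), and that of channels without below 1 or 2 or epicenter 3 (0.0602, 0.127 and 0.0535). The excitatory one ended without below 1, 2 or 4 or epicenter 3 (0.0929, 0.12, 0.0828 and 0.0852) or with library totals (0.0794). The dorsal horn call ended without below 1, 2 or 4 or epicenter 3 (0.0899, 0.140, 0.121 and 0.179), with library totals (0.0886) or with upper-quartile factors (0.0507). That of microglia ended without epicenter 3 (0.0812), monocytes without above 4, below 2 or epicenter 3 or 4 (0.0568, 0.294, 0.109 and 0.0751) and T and NK cells without below 2 (0.0852). Interferon lost its call without below 3 or epicenter 1 or 3 (0.0739, 0.179 and 0.0712), and thoracic-level Hox and dorsal root ganglion genes without below 3 (0.407 and 0.0809). The count of higher dorsal root ganglion genes was 1 without epicenter 4 and 4 without below 4. Of the genes given a fold here, only Hoxc8 kept its call in a fit of only the libraries compared. That fit ended the excitatory and dorsal horn calls and called 31 genes in place of 5062. Without below 3 the count was 11057, without epicenter 1, 2 and 4 it was 3019, 2999 and 2335, and without below 1, 2 and 4 3113, 2884 and 2917. The count of called genes moved over 1.5 times in 22, 19, 10 and 24 of the 36 lists with calls on leaving out epicenter 1 to 4, and in 17, 25, 28 and 22 for those below. For uninjured cord it did so in 7, 10, 9 and 9 lists and for the segments above in 6, 7, 6 and 8.

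Above and below the injury differed in phagocyte, matrix, Schwann cell and Hox genes. Pmp22 was at 108 ± 45.7 CPM above and 609.7 ± 147 CPM below (SD, n = 4 each), a log2 fold change of -2.50 ± 0.23 (SE) with edgeR adjusted p = 1.14e-05, and Atp6v0d2 stood at -5.94 ± 0.64. Phagocytic, monocyte, T and NK cell, antigen presentation, complement, cytokine and reactive astrocyte genes were lower above in 15, 13, 9, 15, 12, 10 and 12 of 16, 14, 16, 15, 14, 18 and 17 cases (16, 13, 12, 15, 14, 12 and 14 adjusted over the list alone). In this order camera gave adjusted p = 2.14e-07, 2.79e-08, 8.81e-06, 4.09e-10, 2.88e-08, 3.58e-04 and 8.81e-06 (adjusted p = 0.412, 0.278, 0.278, 0.300, 0.300, 0.412 and 0.445 with an estimated correlation). Cd74 stood at -2.51 ± 0.34. Lower above were also 18, 12, 4, 9, 3, 13 and 12 of 18, 14, 11, 14, 10, 16 and 14 fibroblast, Schwann cell, meningeal, endothelial, pericyte, lysosome and lipid genes (18, 13, 5, 9, 4, 13 and 12 adjusted over the list alone). For these lists camera gave adjusted p = 5.81e-12, 4.14e-14, 4.74e-05, 1.60e-04, 0.00855, 1.41e-05 and 6.38e-06 (adjusted p = 0.300, 0.278, 0.412, 0.438, 0.477, 0.449 and 0.412 with an estimated correlation). Postn stood at -2.49 ± 0.41 and Drp2 at -2.05 ± 0.14. Neutrophil, B and plasma cell, red blood cell and proliferation genes were lower above in 3, 4, 2 and 2 of 11, 11, 7 and 12 cases (8, 4, 2 and 8 adjusted over the list alone). Camera gave these lists adjusted p = 0.00475, 0.0439, 0.0418 and 0.0131 (adjusted p = 0.511, 0.415, 0.511 and 0.517 with an estimated correlation). Homeostatic microglia and interferon genes were lower in 5 and 2 of 12 and 17 cases (6 and 1 adjusted over the list alone, camera adjusted p = 0.195 and 0.281), the interferon median of 0.03 differing in sign from the test.

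Genes of cholesterol synthesis, myelin and oxidative phosphorylation were higher above than below in 19, 12 and 15 of 19, 16 and 15 cases (19, 14 and 15 adjusted over the list alone). Tested with camera, they had adjusted p = 1.86e-18, 3.70e-10 and 1.74e-07 (adjusted p = 0.278, 0.278 and 0.395 with an estimated correlation). Sqle stood at 1.02 ± 0.09. Genes of general neurons, motor neurons, glutamatergic transmission, GABA and glycine, and channels were higher above in 6, 5, 1, 2 and 2 of 14, 12, 13, 13 and 15 cases, and 1 motor neuron gene was lower (6, 6, 1, 0 and 2 higher adjusted over the list alone). Their camera tests gave adjusted p = 4.31e-05, 0.00169, 0.00503, 9.97e-04 and 4.79e-04 (adjusted p = 0.449, 0.412, 0.488, 0.50 and 0.488 with an estimated correlation). Chodl stood at 1.27 ± 0.31 and Slc17a7 at 6.25 ± 0.77. Level and injury were not told apart. Dorsal horn and dorsal root ganglion genes had 0 and 1 higher and 2 and 0 lower members (camera adjusted p = 0.561 and 0.511). Calca was at 80.4 ± 15.6 CPM above and 12.8 ± 6.13 CPM below (2.65 ± 0.40). Thoracic-level Hox genes were higher above in 7 of 15 cases and lumbar and sacral ones lower in 9 of 11 (8 and 10 adjusted over the list alone). The Hox lists had camera adjusted p = 1.22e-07 and 1.18e-07 (adjusted p = 0.278 and 0.288 with an estimated correlation). Hoxc8 stood at 1.82 ± 0.09 and Hoxd10 at -4.87 ± 0.39. The lumbar and sacral median was -7.23, or -4.87 with members that had no counts in a group set to their bound. Hoxa11 held 3163 counts below and 1 above, a ratio of 3084 (95% counting interval 553 to 121864). The B cell call ended without above 2 or below 1 or 2 (camera adjusted p = 0.0853, 0.0966 and 0.0736) or with library totals (0.112). That of red blood cells ended without above 1 or 3 or below 1 or 2 (0.0733, 0.0570, 0.179 and 0.116) or with library totals (0.0645), and those of pericytes and proliferation without below 3 (0.0603 and 0.12). Without above 2, 3587 genes differed in place of 5788. Leaving out a library moved the count of called genes over 1.5 times in 11, 13, 14 and 10 of 42 lists for above 1 to 4, 8, 8, 11 and 7 for those below, 4, 4, 4 and 4 for uninjured cord and 4, 4, 2 and 4 for the epicenter.

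**Figure D4:**
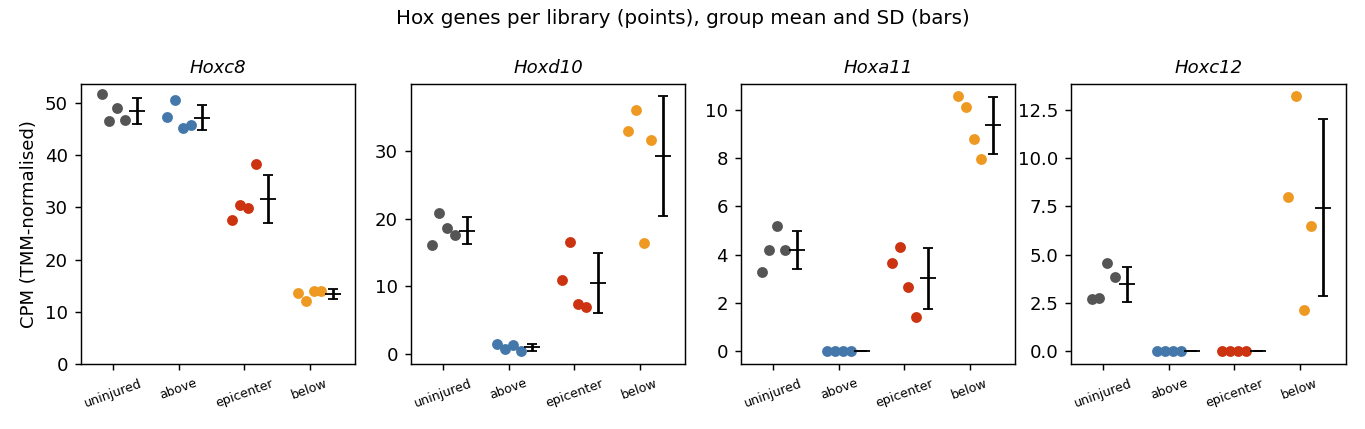
CPM of Hoxc8, Hoxd10, Hoxa11 and Hoxc12 in each library (points), with the mean and SD of each group of 4. Mean Hoxc8 is lowest below the injury, mean Hoxd10, Hoxa11 and Hoxc12 are highest there, and mean Hoxd10 and Hoxa11 are lowest above it.

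Genes specific to a segment numbered 3855 at the epicenter (2056 higher, 1799 lower), 248 below (116 higher, 132 lower) and 36 above (5 higher, 31 lower). At the epicenter they included 11 of 11 neutrophil genes, 7 of 7 red blood cell genes, 7 of 11 B and plasma cell genes and 11 of 18 fibroblast genes, all higher, and 5 of 15 voltage-gated channels, lower. Fits of only the libraries compared allowed at most 31 each at the epicenter and below. Above, 4 lumbar and sacral Hox genes were specifically lower, Hoxd10 and Hoxa11 among them. The 5 higher genes, Hoxa9, Ttyh1, E330020D12Rik, Gm29629 and Gm53, are named after their values were seen. The higher genes numbered 1 without above 1 and 21 without below 3. Against uninjured cord edgeR did not call Ttyh1 or Gm53 without any 1 of the uninjured or above libraries (adjusted p up to 0.108 and 0.109), Hoxa9 without any uninjured, above or epicenter library or below 1 (up to 0.144), or E330020D12Rik without any uninjured library, above 1, 3 or 4, epicenter 1 or 3 or below 1 or 4 (up to 0.160). Against the epicenter, Gm53 lost its call without above 1, 3 or 4 or epicenter 1, 2 or 4 (edgeR adjusted p up to 0.0932) and E330020D12Rik without above 1 or 4 or epicenter 2 (up to 0.0775), and against below Ttyh1 without above 3 or 4 (up to 0.0692) or with library totals (0.171). Calls against uninjured cord ended with upper-quartile factors for Hoxa9 and E330020D12Rik (edgeR adjusted p = 0.0570 and 0.0560), with no filter for Hoxa9 and Ttyh1, with the strict filter for Hoxa9, with limma-voom, also with duplicateCorrelation, for Hoxa9, E330020D12Rik and Gm53 and with glmTreat for all 5, and Gm53's call against the epicenter with the strict filter. Below, 3 cholesterol synthesis and 3 thoracic-level Hox genes were specifically lower and 2 lumbar and sacral Hox genes higher. The epicenter count was 2410, 2409 and 1882 without epicenter 1, 2 and 4 and 2382, 2129, 9231 and 2344 without below 1 to 4. The count above was 23 without above 2 and 59 without below 3. The count below was 159, 163 and 156 without uninjured 2, 3 and 4, 158 without above 2, 132, 127, 648 and 118 without epicenter 1 to 4 and 121 without below 4.

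The 3 segments share their uninjured libraries, which by itself can make calls overlap. Epicenter and below shared 8206 genes called in the same direction (5135 higher, 3071 lower), with 20 in opposite directions. Epicenter and above shared 791 (723 higher, 68 lower) with 3 opposite, and above and below 756 (713 higher, 43 lower) with 13 opposite. Independent lists would share 1790 and 1098, 235 and 31.1, and 173 and 16.7 higher and lower genes, and simulated unchanged groups 0. With the uninjured libraries split 2 and 2, fewer per test, the pairs shared 4655 to 5456, 97 to 153 and 90 to 144 genes over 6 splits. The covariance of log2 fold changes was 1.28, 0.584 and 0.446 (mean 1.30, 0.584 and 0.439 when split) against simulated 0.0487, 0.0488 and 0.0482. The correlation across genes, which are not independent replicates, was 0.922, 0.733 and 0.715 against 0.508, 0.507 and 0.509. Without uninjured 1 to 4 and above 1, epicenter and above shared 387, 441, 392, 448 and 443 genes and above and below 365, 423, 375, 428 and 424. Without below 2 and 3 these were 1198 and 2174, and 1156 and 1908.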

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

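The tests of below replicate 3, of dorsal root ganglion tissue in the segment below and of nerve roots were chosen after the result was seen, and those of ganglion tissue at the epicenter, of spinal level and of other splits before.

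Below replicate 3 lay apart from the other below libraries in 7 list means and 9 genes, with lower neuronal and Hox levels and higher endothelial, pericyte and ependymal ones, where chance sets about 1 in 20 groups apart. A label exchanged with an epicenter library was argued against, since its lumbar and sacral Hox mean of 1.18 log2 CPM lay 1.47 above the highest epicenter library (-0.29, epicenter SD 0.52), though under the other below libraries (2.29 to 2.86). Epicenter tissue mixed into the segment was argued against by its general neuron mean of 6.85 log2 CPM, a difference of -0.81 from the lowest epicenter library (7.67, epicenter SD 0.28), with the other below libraries at 8.42 to 8.86. Library size was argued against by its total of 79.2 M counts, between the 73.7 and 90.0 M of the others. A wider injury or another position of this segment may remain as candidate explanations, and no biological explanation was tested, since the labels give none for a single library.

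Schwann cell genes were higher at the epicenter and below, 14 and 13 of 14, of which 12 reached 1 CPM in uninjured cord and 0 are in another list; Pmp22, an abundant member, was at 80.3 ± 7.47, 108 ± 45.7, 660.5 ± 61.9 and 609.7 ± 147 CPM in uninjured cord, above, at the epicenter and below, and Drp2 at 63.0 ± 4.77, 68.4 ± 9.56, 168 ± 30.5 and 283 ± 35.6 CPM. Dorsal root ganglion tissue in the segment below was argued against, since edgeR called 0 of 8 ganglion genes there (1 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0), with Calca at 21.3 ± 1.91 CPM in uninjured cord and 12.8 ± 6.13 below. At the epicenter ganglion tissue stays open: without replicate 4, 4 of the 8 genes were still called higher (7 with it) beside 14 of 14 Schwann genes, Calca was at 119 ± 83.1 (80.4 ± 15.6 above, where it alone of the 8 was called) and Scn10a at 6.63 ± 12.5 CPM (replicate 4 at 243 and 25.3, the others at 64.6 to 90.9 and 0.0938 to 0.761), and of these 8 genes 2 reached 1 CPM in uninjured cord and 0 are in another list. Nerve roots left on the segments cannot be told apart from the groups, because the lowest epicenter or below library lay 1.37 above the highest uninjured or above one (5.30 against 3.92 log2 CPM; SD 0.17 at the epicenter, 0.37 below, 0.51 in uninjured cord and 1.08 above) but roots may be denser at some levels than at others. The injury itself, with Schwann cells inside the cord, stays open as well and was not tested.

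Lumbar and sacral Hox genes were lower above and at the epicenter than in uninjured cord, which pools the levels. If spinal level alone set this, the mean of the 3 injured segments would match uninjured cord. The median log2 ratio over 11 genes was -0.54 (SD 1.14, range -3.13 to -0.00422), with 5 genes within 0.5 of 0, a value between the bounds set for either outcome. Level and injury cannot be told apart, since no uninjured segment of a single level was analysed here. Uninjured 4 held 124 CPM of Hoxc11 (other uninjured 3.64 to 5.49), and this 1 library puts the median over 0.5 from 0. The injury stays open, untested.

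By Dixon's test at the 95% level, a library whose gap to its nearest neighbour takes over 0.83 of the range of its 4 libraries stands apart; 51 of 524 groups of values met this, where chance gives about 1 in 20, or 26.2. Values are log2 CPM (means over a list), with those of the other 3 libraries of the group after "against". Below replicate 3 stood apart in the lists of endothelium (5.84 against 4.94 to 5.03), pericytes (4.88 against 3.81 to 3.91), glutamatergic transmission (3.74 against 5.35 to 5.54), GABA and glycine (4.56 against 6.58 to 6.95), dorsal horn (2.87 against 4.32 to 4.48), ependymal cells (3.08 against 2.12 to 2.27) and thoracic-level Hox (3.98 against 4.6 to 4.65), and in Rbfox3 (3.98 against 6.49 to 6.99), Snap25 (7.80 against 10.31 to 10.70), Gad1 (5.13 against 7.21 to 7.43), Slc17a6 (4.79 against 7.07 to 7.41), Gabrb2 (1.58 against 4.24 to 4.78), Glra3 (0.86 against 3.19 to 3.36), Hoxd10 (4.03 against 4.98 to 5.17), Gad2 (5.05 against 7.02 to 7.31) and Scn2a1 (4.75 against 6.52 to 6.72). Above 1 did so in the lists of complement (4.69 against 4.07 to 4.17), fibroblasts (4.87 against 3.44 to 3.51), Schwann cells (3.92 against 1.66 to 1.98) and meninges (3.54 against -0.05 to 0.28), and in Col1a1 (6.14 against 3.29 to 3.51), Pmp22 (7.46 against 6.4 to 6.43), Drp2 (6.37 against 5.98 to 6.00), Col3a1 (5.54 against 2.02 to 2.29) and Aspn (1.16 against -0.01 to 0.00). Below 2 did so in the lists of monocytes (0.95 against 1.98 to 2.18) and T and NK cells (-1.11 against -0.29 to -0.15), and in Cd74 (5.47 against 6.4 to 6.57) and H19 (2.41 against 4.85 to 5.09). Above 4 did so in the list of neutrophils (0.23 against -1.40 to -1.25), and in Serpina3n (7.99 against 7.79 to 7.80), S100a8 (2.18 against 0.29 to 0.55) and S100a9 (2.99 against 0.95 to 1.00). Epicenter 4 did so in the list of dorsal root ganglion (4.14 against -0.06 to 0.26), and in Serpina3n (9.03 against 9.58 to 9.65), Hoxc9 (4.41 against 3.93 to 4.00) and Slc17a7 (1.44 against -2.38 to -1.86). Uninjured 1 did so in Cd79a (-3.03 against -1.94 to -1.75). Uninjured 2 did so in the list of reactive astrocytes (3.04 against 2.91 to 2.93). Uninjured 3 did so in the list of skeletal muscle (-1.62 against -1.94 to -1.89), and in Chat (4.73 against 4.83 to 4.84) and Cst7 (-1.28 against -1.80 to -1.73). Uninjured 4 did so in Hoxc11 (6.95 against 1.87 to 2.46). Above 3 did so in Hoxa11 (-4.76 against -5.29) and Hoxc12 (-4.76 against -5.29). Epicenter 1 did so in the list of proliferation (1.78 against 2.07 to 2.12), and in Col6a3 (5.81 against 6.62 to 6.67). Epicenter 2 did so in the list of endothelium (4.96 against 5.21 to 5.25), and in Hoxc11 (1.87 against -1.70 to -1.18). Epicenter 3 did so in Rbfox3 (5.53 against 6.11 to 6.23). Below 1 did so in the list of interferon response (3.62 against 3.04 to 3.09). For Hoxa11 and Hoxc12 above 3 holds 1 count, and the others above hold 0.

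Some genes were called in opposite directions by edgeR against the same uninjured libraries: 3 at the epicenter and above, 20 at the epicenter and below and 13 above and below, each of them also called in the direct comparison of the segments. The first were RP23-411M4.2 (0.54 at the epicenter and -1.25 above), Ptger2 (0.51 and -0.66) and Gm15564 (0.71 and -0.85), named after their values were seen. RP23-411M4.2 lost its epicenter call without any uninjured library, above 1 or 2, epicenter 2, 3 or 4 or below 1 or 2 (edgeR adjusted p = 0.0525 to 0.150) or with upper-quartile factors (0.0723), Ptger2 its above call without uninjured or above 1, 2 or 4 (0.0737 to 0.0905), and Gm15564 that without uninjured 2 (0.0559) or above 3 (0.0532). Lars2 (0.94 at the epicenter and -0.75 below) was among the 20. Hoxa11, lower above and higher below by 1.15, was among the 13.

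Other splits of the same libraries into groups of the same sizes were counted, with under 5% of them as large. Libraries may share an animal, so chance is not excluded. In fits of only a pair's 8 libraries, 1 of 35 splits (the real one, the lowest share possible) gave as many genes in all 6 comparisons. Against uninjured cord these were 15006 at the epicenter, 3684 above and 6446 below. Between segments they were 12917 (epicenter, above), 31 (epicenter, below) and 1643 (above, below). The highest other splits gave 0 genes, and 1 for above against below. Of 100 splits of all 16 libraries, 1 gave as many genes specific to the epicenter (3855, highest other 2296) or to the segment below (248, highest other 0), and 1 as many shared by epicenter and above (791, 550), epicenter and below (8206, 808) or above and below (756, 637). The rule names genes called in the real grouping, so their count (729 in 1 split, highest other 252) decides nothing. As many list calls came from 2 of 100 splits (168, highest other 173). As many genes specific to the segment above came from 3 (36, highest other 3121), and neither count stands out by size. The split with 3121 placed all 4 epicenter libraries together as that segment, which points to a structure of the samples.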

How the results depend on the processing

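Limma-voom with library quality weights and leaving out above 1 and below 3 together were chosen after the data were seen, and the other settings before.

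For differing genes, glmTreat, which asks for more than a 1.5-fold change, gave 5877, 252 and 2579 at the epicenter, above and below against uninjured cord, 3405 for epicenter against above, 85 for epicenter against below and 993 for above against below; 62, 16 and 5 genes specific to epicenter, above and below; and 238, 2467 and 225 shared by epicenter and above, epicenter and below, and above and below. It asks for larger changes by construction; for the other settings the cause was not tested. Above against uninjured, DESeq2 gave 1464 genes, limma-voom 269, duplicateCorrelation 278, only the libraries compared 3684, library weights 3552 and leaving out above 1 and below 3 1661, in place of 841. Epicenter against below, only the libraries compared gave 31, library weights 11496 and leaving out both 11268, in place of 5062, and above against below only the libraries compared gave 1643 in place of 5788. Genes specific to the epicenter (3855) numbered 9542 with library weights and 9541 without both, those above (36) 19 with the strict filter, 162 with weights and 64 without both, and those below (248) 467 with library totals, 159 with no filter and 789 with weights. Shared by epicenter and above (791) were 1344 with DESeq2, 243 with limma-voom, 250 with duplicateCorrelation, 3167 with weights and 1559 without both, and by above and below (756) 1275, 228, 235, 2768 and 1428. Other settings moved these counts by at most 1.5 times, the replicate block aside.

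Leaving out each library in turn gave 13489 to 15826 genes at the epicenter, 408 to 2298 above and 7422 to 11135 below against uninjured cord, 10813 to 14321 for epicenter against above, 2335 to 11057 for epicenter against below and 3587 to 8262 for above against below. Specific genes ranged from 1882 to 9231 at the epicenter, 23 to 59 above and 118 to 648 below, and shared ones from 387 to 2174 for epicenter and above, 6592 to 9654 for epicenter and below and 365 to 1908 for above and below. Called list tests ranged from 160 to 174 and called named genes from 692 to 782.

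With the replicate number as a block, which the labels give in all groups, epicenter against below gave 2567 genes (894 higher, 1673 lower), epicenter against above 5514 higher and 6637 lower, and 1932 genes were specific to the epicenter and 164 to the segment below; other counts moved by less than 1.5 times. The numbers are not known to mark the same animal and were not taken to pair the samples: the correlation of deviations of same-numbered libraries was over 0.1 in 3 of 4 pairs of epicenter and below (0.0789 to 0.309), 2 of 4 of above and epicenter, 1 of 4 of above and below and 0 of the pairs with uninjured cord, with a consensus of 0.0996. As a hint from the data, all 4 epicenter libraries correlated best with the below library of their own number. The block changed 4 list calls, 2 ended and 2 gained.

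Of 168 list calls, 0 passed camera with an estimated correlation, at 40 unadjusted p under 0.05, and fry ended 23 and gained 14. Calls ended and gained among the 252 list tests were 0 and 1 with RLE factors, 3 and 0 with upper-quartile factors, 5 and 4 with library totals, 0 and 17 with no filter, 11 and 0 with the strict filter, 3 and 15 with DESeq2, 12 and 14 with glmTreat, 7 and 14 with only the libraries compared, 1 and 0 with duplicateCorrelation, 8 and 17 with weights and 10 and 19 without both. Among 510 values of 85 genes (fewer where a setting gave none) they were 1 and 0, 6 and 1, 12 and 11, 9 and 0, 2 and 5, 0 and 13, 63 and 18, 28 and 14, 12 and 60 and 5 and 47 in that order without glmTreat, and 32 and 12 with limma-voom; glmTreat left 395 of the 510 as they were, ended the rest and gained 0. The glycolysis list below against uninjured cord turned direction with glmTreat (adjusted p = 0.791 by camera on its ranks, 0.0303 before). Limma-voom had no separate list test, as camera uses its values. With only the libraries compared, specific and shared genes were not counted. Depth limits genes near 3 counts, and a simulated 1.5-fold change was called in 40% of genes.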

Other observations

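All lists described here were fixed before the data were examined, and no test of them was chosen after its result was seen.

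Some genes of nerve regeneration and of recent cell activity rose in each injured segment against uninjured cord. Regeneration-associated genes, which injured neurons and glia induce, rose in 9 of 13 cases at the epicenter (2 lower), 8 below (1 lower) and 3 above. Adjusted over the list alone, 9, 8 and 5 rose. In these segments camera gave adjusted p = 0.0114, 0.00169 and 4.65e-06 (adjusted p = 0.300, 0.278 and 0.221 with an estimated correlation). The count above was 2 without uninjured 1 or 2 and 6 without below 3. Immediate early genes, which are induced within minutes of stimulation, rose in 9 of 12 cases at the epicenter, 9 below and 2 above, with 1 lower at the epicenter and 1 below. Adjusted over the list alone, 9, 9 and 6 rose. Their camera tests gave adjusted p = 0.00216, 0.00127 and 0.00225 (adjusted p = 0.387, 0.371 and 0.387 with an estimated correlation). The count above was 1 without uninjured 1 or 2 or above 1, and 4 higher and 1 lower without below 2 and 5 and 1 without below 3. Iron and heme genes rose in 7 of 12 cases at the epicenter and 6 below, and 2 and 1 fell (7 and 6 higher adjusted over the list alone). This list had camera adjusted p = 0.0959 at the epicenter and 0.0327 below, the latter 0.495 as an adjusted p with an estimated correlation and 0.0573 without below 3. Above, 1 rose (4 adjusted over the list alone, camera adjusted p = 0.0525), or 3 without below 2 or 3. Hmox1, heme oxygenase, went from 4.66 ± 0.296 CPM in uninjured cord to 39.7 ± 6.49 at the epicenter (3.09 ± 0.31) and rose by 2.48 ± 0.30 below (log2, SE).

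Genes of ependymal cells and motile cilia rose below in 6 of 14 cases (6 adjusted over the list alone), with camera adjusted p = 0.00279 (adjusted p = 0.455 with an estimated correlation), a count of 4 without uninjured 1 and 10 without below 1. Below 3 stood apart in this list (3.08 log2 CPM against 2.12 to 2.27), whose median was 0.30 without it in place of 0.54 (camera adjusted p = 0.00891). At the epicenter 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.439). They were lower above than below in 10 cases (11 adjusted over the list alone), with camera adjusted p = 3.39e-04 (adjusted p = 0.425 with an estimated correlation). That count was 4, 3, 5 and 3 without above 1 to 4, and 3 lower with 1 higher without below 3. Oligodendrocyte progenitor genes rose in 3 and fell in 4 of 11 cases at the epicenter, and in 2 and 5 below, as many as adjusted over the list alone (camera adjusted p = 0.474 and 0.227). Without uninjured 1 or 2 the counts below were 1 and 3. Glycolysis genes rose in 4 and fell in 7 of 15 cases at the epicenter, and in 3 and 8 below (7 and 9 lower adjusted over the list alone). The glycolysis list had camera adjusted p = 0.268 and 0.0303, the latter 0.465 as an adjusted p with an estimated correlation, 0.0724 without below 3, 0.0651 without below 4 and 0.0548 with library totals. Its median and mean below were -0.29 and 0.07, of opposite sign, as were -0.20 and 0.21 at the epicenter. Homeostatic astrocyte genes rose in 2 and fell in 5 of 14 cases at the epicenter (4 and 7 without below 3), and in 4 and 5 below, where the median of 0.04 and the downward test differ in sign. Chondroitin sulfate proteoglycan genes rose in 3 and fell in 5 of 13 cases at the epicenter, with a median of 0.06 and a mean of -0.08, and in 3 and 4 below. Adjusted over the list alone, higher and lower genes numbered 4 and 6 for astrocytes and 3 and 5 for proteoglycans at the epicenter, and 4 and 5 and 4 and 4 below. Camera gave the astrocyte list adjusted p = 0.333 and 0.616, and proteoglycans 0.474 and 0.474. Of other tissues, skeletal muscle genes rose in 5 and fell in 1 of 10 cases at the epicenter, and in 4 and 1 below (3 and 0 without any 1 uninjured library, 2 and 1 without below 4), the same numbers as adjusted over the list alone. Fat genes rose in 2 and fell in 2 of 5 cases at the epicenter, and in 1 and 1 below (1 and 2 without epicenter 1, 2 and 2 without below 2), with 2 lower below adjusted over the list alone. The muscle and fat lists had camera adjusted p = 0.317 and 0.927 at the epicenter and 0.188 and 0.637 below, and the fat medians of -0.13 and -0.60 differ in sign from the means of 1.35 and 0.71.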
